A study of Mus musculus with 2 samples.

How the data were processed

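The series holds 2 Affymetrix Mouse Genome 430 2.0 arrays, per the series' design text, 1 of RNA from sorted CD4 IEL and 1 of RNA from sorted CD4CD8aa IEL, both from RAG-knockout recipients of naive CD4 T cells 8 weeks after the transfer. Per the labels' protocols, IEL were prepared by density gradient centrifugation on Percoll, RNA was extracted with TRIzol, and biotinylated cRNA was made by the standard Affymetrix protocol. The arrays have 1 colour. Signals were made with GCOS 1.2, per the submitters' processing notes, and the data were analysed in GeneSpring GX10, per the series' design text. The background correction and summarisation of probes into probe sets, the number of animals pooled, the antibodies and the gates of the sort are not given in the sources used here.

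The authors deposited intensities of 45101 probe sets per array in 2 forms. The raw intensities, so named per the file headers, had a 2% trimmed mean of 500 on each array, and ranged from 0.2 to 56266.9 in CD4 IEL and from 0.3 to 64980.5 in CD4CD8aa IEL. The normalized intensities, so named per the file headers, equal the raw ones divided by their array's median (82.5 and 81.1), to within 4.98e-08, as a check of the values showed. The authors' deposited table also gives a log2 fold and a linear fold, which per the file headers are CD4 over CD4CD8aa and thus have the opposite sign to the differences reported here; the deposited log2 values and the unfloored log2 differences computed here summed to 0 within 2.55e-07 for every probe set. A deposited filter column, per the file headers, takes the values 0, 1 and 2. It equals the number of arrays on which the raw signal lies in the lowest 20% for 45078 probe sets and differs for 23 with tied signals. The 2 columns of present or absent calls carry no sample name and were not used, and since the filter column that sums them follows signal rank, they are not treated as Affymetrix detection calls.

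Before the data were examined, the groups, the size rules, the rule for the named genes, the 28 gene lists and the processing alternatives were fixed, apart from the added ones named below. The design set a detection floor from detection calls, or from a percentile where the files give no such calls, and the percentile was used here. The values come from the full-precision normalized intensities. Intensities below 0.4 times the array median, the higher of the 30th percentiles of the arrays, were raised to that floor before log2, and a probe set was detected where the brighter array lay above it. Above the floor were 31561 probe sets in CD4 IEL and 31525 in CD4CD8aa IEL. Where the dimmer array lay at the floor the fold is a lower bound, written "at least". No further scaling was applied, since the deposited values were already divided by their array's median.

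Of the probe sets, 64 are controls and were left out of all gene counts, 37782 name 1 gene symbol in the deposited table, 1399 name several and were used for no gene, 5821 name none and 35 carry a symbol turned into a date by a spreadsheet and were left out. Each gene took the probe set with the highest mean log2 signal, which gave 20663 genes, of which 17376 were detected on at least 1 array and 14033 on both. Against RefSeq gene names, 16146 of the symbols were current, 2131 were older synonyms and 2386 were not found, and symbols are printed as deposited. The lists hold 506 distinct genes, of which 476 matched a probe set, 8 of them through a synonym. Genes are identified by these symbols, and positions are not given because no genome build is named in the sources used here.

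With 1 array per group there is no test, standard error or p-value. The comparison is described by log2 differences (CD4CD8aa IEL minus CD4 IEL), by counts of detected genes at least 2-fold apart, and for each gene list by the median over its detected members, the members at least 2-fold higher, at least 2-fold lower and between, and the percentile of the median among 10000 random lists of the same size, drawn within 20 bins of mean log2 signal. The percentile describes these arrays only. A technical spread was taken from 20185 detected probe sets of 7380 genes that have several, as the SD of their log2 differences around the gene's mean within bands of signal. It was 0.807 below the array median, 0.674 from 1 to 2 times, 0.554 from 2 to 4 times, 0.453 from 4 to 16 times, 0.411 from 16 to 64 times and 0.354 above. It holds true differences between transcripts of a gene as well as noise, and covers neither animals nor RNA preparations. The number of arrays limits the precision of every value.

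The named genes are Cd4, Cd8a, Cd8b1, Zbtb7b and Runx3; the 10 detected genes with the largest difference in each direction, without genes that have another detected probe set at least 2-fold the other way; from every list the member with the largest difference in each direction if at least 2-fold, and up to 4 for the lists on helper lineage, CD8 lineage, cytotoxic genes, NK receptors, homing, Th1, Th17, regulatory T cells, inhibitory receptors and T cell receptor signalling; and the 3 most abundant members of each list of another cell type. The lists of other cell types are those of the small intestinal epithelium, B and plasma cells, myeloid and dendritic cells, mast cells, gamma-delta T cells and natural IEL, and fibroblasts and endothelium. Some genes that this rule names are not reported here. Other genes are said where they stand to have been chosen after their values were seen.

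The alternatives were median centring over detected probe sets, quantile normalization, no floor, a floor 2 times as high, no detection filter, detection on both arrays, the median over a gene's detected probe sets, leaving out probe sets whose identifier ends in _x_at, the raw intensities, thresholds of 1.5-fold and 3-fold, and random lists matched on the brighter array. Floors at 2 and at 4 times the array median, and the CD8 lineage list without Cd8a or without Cd8a and Cd8b1, were added after the data were seen. The steps were tested on simulated data in 20 runs of 20663 genes with the real mean signals and 200 genes changed. Noise was drawn at random from the observed same-gene deviations in the gene's band of signal. Of 4-fold changes 98.5% and of 8-fold changes 99.9% came out at least 2-fold in the right direction. Of 400 unchanged lists of 16 genes, 4% fell outside the central 95% of their random lists, and every list lowered 4-fold lay at percentile 0. The changed genes, and with them the lowered lists, were drawn only from genes well above the floor. The recovery of changes in dim genes was therefore not tested. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.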

Results

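Gene expression was measured in intraepithelial lymphocytes (IEL), the T cells that lie between the epithelial cells of the gut, from the small intestine of mice in the T cell transfer model of colitis. In this model naive CD4 T cells are given to RAG-knockout mice, which make no T or B cells of their own, and the transferred cells expand and reach the gut. Cells were taken 8 weeks after the transfer, on the C57BL/6 background, and were sorted into CD4 cells without CD8 alpha (CD4 IEL) and CD4 cells that carried CD8 alpha as well (CD4CD8aa IEL). CD8 alpha-alpha homodimers are a surface marker of many gut T cells. RNA of each population was hybridised to 1 single-colour mouse array with 45101 probe sets. Each group thus has 1 array and no replicates, the number of animals behind each RNA is not given in the sources used here, and every difference below compares these 2 arrays and carries no test. Signals are given as multiples of the array median, and differences as log2 CD4CD8aa IEL minus CD4 IEL. Before that division the median signal was 82.5 on the CD4 array and 81.1 on the CD4CD8aa array, and 70.0% and 69.9% of the probe sets lay above the floor of 0.4 times the array median. Across the 17376 genes detected on at least 1 array, the log2 signals had a Pearson correlation of 0.961, taken across genes, which are not independent replicates. The only spread that could be measured was that between probe sets of the same gene, whose log2 differences had an SD of 0.807 below the array median and of 0.354 above 64 times the median.

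The comparison asks how CD4 T cells of the gut epithelium that carry CD8 alpha differ in transcription from those that do not. Of the 28 gene lists examined, the Th17 list had the largest median difference. Il17a, the cytokine that defines Th17 cells, had a signal of 222.6 in CD4 IEL and of 4.11 in CD4CD8aa IEL, 54.1-fold lower, and 11 of the 16 detected Th17 genes were at least 2-fold lower. Genes of naive and recirculating T cells were also lower in CD4CD8aa IEL, among them Klf2 (10.3-fold) and Satb1 (3.46-fold), as was Zbtb7b, the transcription factor that fixes the CD4 helper lineage (2.84-fold). Genes of the CD8 lineage, also without the sorted marker, and of cytotoxic cells were modestly higher as groups, with Crtam 3.31-fold and Klrd1 2.86-fold higher, while Gzma and Gzmb lay within 2-fold. The costimulatory receptor Cd28 was 25.4-fold lower, whereas 20 of the 24 genes of the T cell receptor complex and its signalling lay within 2-fold.

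The sorted markers check the labels and are no finding. Cd8a had a signal of 3.79 in CD4 IEL and 291.4 in CD4CD8aa IEL, 76.8-fold higher, and its 5 probe sets were between 9.14-fold and 116-fold higher. Cd4 was bright on both arrays, at 72.6 and 86.4, a log2 difference of 0.25, and its dimmer probe set gave -0.37. Cd8b1, which encodes the CD8 beta chain of conventional CD8 T cells, stayed near the array median, at 0.51 and 1.29, a log2 difference of 1.33 at a signal where same-gene probe sets had an SD of 0.81, and of 0.69 with the floor 2 times as high. Zbtb7b had signals of 4.91 and 1.73, a log2 difference of -1.51. Runx3, the transcription factor that opposes it in CD8 cells, had 41.4 and 54.1, a log2 difference of 0.38, which is within the same-gene SD of 0.41 at that signal. With the floor raised to 4 times the array median, an alternative chosen after the data were seen, the difference of Zbtb7b was -0.30.

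Of the 17376 detected genes, 1156 were at least 2-fold higher and 1088 at least 2-fold lower in CD4CD8aa IEL, together 12.9%. Most of these genes were dim: 1518 of the 2244 had a signal under 2 times the array median even on the brighter array, and for 1069 the dimmer array lay at the floor, so that the fold is a lower bound. In simulated array pairs that carried only the same-gene spread and 200 changed genes, a mean of 583 unchanged genes came out at least 2-fold higher and 653 at least 2-fold lower. That spread came from floored differences and was floored again, which shrinks the noise of dim genes. It leaves out animals and RNA preparations but holds true differences between transcripts. How many of the observed differences are real therefore cannot be read from the simulated means. The large differences leaned towards lower signal in CD4CD8aa IEL. At least 4-fold, 68 genes were higher and 167 lower, and at least 8-fold, 2 were higher and 41 lower. With the floor set at 2 times the array median, also chosen after the data were seen, 204 genes were higher and 219 lower by at least 2-fold among 9860 detected genes, against simulated means of 151 and 136 unchanged genes, and 9 were higher and 48 lower by at least 4-fold.

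**Figure D1:**
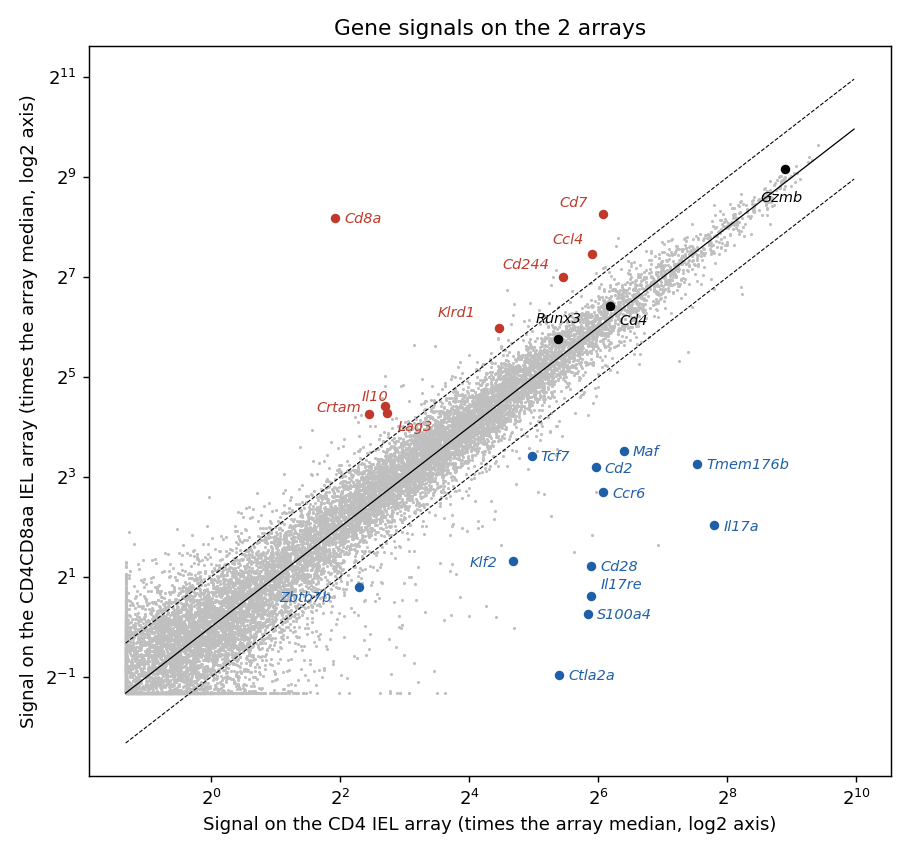
Signals of the 17376 detected genes on the CD4 IEL array (horizontal) and the CD4CD8aa IEL array (vertical), in multiples of the array median on log2 axes, with signals raised to the floor of 0.4. The solid line marks equal signals and the dashed lines 2-fold differences. Genes named in red (among them Cd8a, 76.8-fold) were higher and genes in blue (among them Il17a, 54.1-fold) lower in CD4CD8aa IEL, while Cd4, Runx3 and Gzmb, in black, lie near the line of equal signals. Tmem176b, Ccr6, Maf and Gzmb were chosen for display after their values were seen.

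Th17 genes had a median log2 difference of -3.66 over 16 detected members, 12.6-fold lower in CD4CD8aa IEL and below all 10000 random lists matched on signal, of which the central 95% had medians between -0.17 and 0.29. No member was 2-fold higher and 5 lay between. Il17re, a subunit of the receptor for IL-17C, had signals of 59.4 and 1.54 (38.6-fold lower), Ltb4r1, the leukotriene B4 receptor, 26.0 and 0.99 (26.2-fold lower), and Il1r1, the receptor for IL-1, 10.96 and 0.54 (20.3-fold lower). Further members were picked out after their values were seen. Ccr6, the chemokine receptor of Th17 cells, was 10.4-fold, Maf 7.30-fold and Tmem176b 19.2-fold lower. Rora, Batf and Stat3, transcription factors with roles in other T cells as well, had log2 differences of 0.34, 0.08 and 0.05. The probe set that names Il22 together with its near-identical copy Iltifb, also picked out afterwards, had 182 and 10.5, 17.3-fold lower, and cannot tell the copies apart. With the floor at 4 times the array median the list's median was -1.45, with Il17re at -3.89, Ltb4r1 at -2.70 and Il1r1 at -1.45.

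Genes of naive, central memory and recirculating T cells had a median log2 difference of -1.34 over 16 detected members, below all random lists, with 2 higher, 9 lower and 5 between. Klf2, which drives the exit of T cells from tissue by way of S1pr1, had signals of 25.6 and 2.49, a log2 difference of -3.37. Helper lineage regulators and surface genes had a median of -0.43 over 15 members (percentile 0.03 of the random lists), with 1 higher, 6 lower and 8 between. This median is the value of Id3 (signals of 0.54 and 0.14), which the floor limits, and it was -0.93 both without a floor and with the floor 2 times as high. The median of the first list was -1.67 and -0.85 under these 2 alternatives. Besides Zbtb7b, the transcription factors Lef1 (log2 difference -2.04), Satb1 (-1.79) and Tcf7 (-1.54, but -0.55 at its other probe set) were lower, each with at least 2 detected probe sets that gave the same direction, and Tox was higher (1.10). Some of these genes stand in both lists. With the floor at 4 times the array median the medians of these lists were -0.36 and -0.28, and Lef1 (-0.28) and Tox (0.50) no longer reached 2-fold.

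Genes of the CD8 lineage had a median log2 difference of 0.56 over 17 members, above all random lists, with 5 higher, 1 lower and 11 between. These values include Cd8a, the marker of the sort. Without it, an alternative chosen after the data were seen, the median was 0.48 over 16 members (percentile 99.98) with 4 higher, and without Cd8a and Cd8b1 it was 0.40 over 15 (percentile 99.88) with 3 higher. Apart from Cd8a, the higher members were led by Crtam, an adhesion receptor of cytotoxic cells (signals of 6.46 and 21.4, log2 difference 1.73), Ikzf3, the transcription factor Aiolos (38.5 and 114, 1.57), and Klrd1, which encodes the NK receptor chain CD94 (22.2 and 63.3, 1.51). Eomes, a T-box factor of memory CD8 T cells, was lower (-2.35) at signals of 2.17 and 0.43, but by only -0.12 with the floor at 2 times the array median. Cytotoxic granule and killing genes had a median of 0.38 over 21 members (percentile 99.95), with 1 higher (Crtam), 1 lower (Gzmc, -1.21, or -0.38 with the floor at 4 times the array median) and 19 between. Gzma, picked out after its values were seen like the next 3 genes, had 615 and 683, and Gzmb 479 and 573, log2 differences of 0.15 and 0.26. The highest signal of any probe set was 682 on the CD4 array and 801 on the CD4CD8aa array. Both granzymes thus lay towards the top of the range, and whether this compressed their differences was not tested. Prf1, which encodes perforin, had 8.16 and 13.1, a log2 difference of 0.68. Tbx21, the T-box factor of Th1 and cytotoxic cells, had 27.0 and 44.1, a log2 difference of 0.71.

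NK cell receptors and adaptors went both ways, with a median of 0.09 over 18 members (percentile 63.0), 4 higher, 3 lower and 11 between. Cd244, a receptor of the SLAM family, was bright and higher (44.1 and 129, log2 difference 1.55), as was Klrd1. Klre1 and Klra5 were higher, at least 2.64-fold and at least 2.41-fold, from CD4 signals below the floor (0.165 and 0.241) to signals near the array median (1.06 and 0.96), and with the floor 2 times as high their log2 differences were 0.40 and 0.27. Klrc1 (-2.41), Klrk1 (at least 4.07-fold) and Klrb1c (just past 2-fold) were lower, all from signals under 3 times the median. Klrb1c was at -0.82 with the floor 2 times as high and under 2-fold with median centring or quantile normalization too, and Klrc1 at -0.45 with the floor at 2 times the array median. Th1 genes had a median of -0.02 over 18 members (percentile 19.6), with 2 higher, 4 lower and 12 between. The chemokines Ccl4 and Ccl3 were 2.94-fold and 2.91-fold higher. Csf2, which encodes GM-CSF, was 4.19-fold lower, Il18r1, the IL-18 receptor, 3.80-fold, Il12rb2 2.42-fold (-0.69 on the log2 scale with the floor at 2 times the array median) and Tnf 2.11-fold lower. Ifng, picked out after its values were seen, was bright on both arrays, at 263 and 354, a log2 difference of 0.43.

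Th2 genes had a median of -1.09 over 11 detected members (percentile 0.01), with 0 higher, 7 lower and 4 between, but most members were dim, and the median was -2.07 without a floor and -0.76 with the floor 2 times as high. Il1rl1, the IL-33 receptor, had the largest difference, with a signal of 4.43 in CD4 IEL, at least 11.1-fold lower in CD4CD8aa IEL, while its other probe set gave -0.21 and the floor at 4 times the array median -0.15. With the floor at 4 times the array median, 3 members remained, with a median of -0.15 (percentile 17.5). Regulatory T cell genes had a median of -0.77 over 16 members, below all random lists, with 2 higher, 4 lower and 10 between. Ebi3, a subunit of IL-27 and IL-35, had signals of 6.75 and 0.84 and was 8.00-fold lower, Tnfrsf4, which encodes OX40, 5.65-fold, Nrp1 2.32-fold and Il2ra 2.28-fold lower. These differences were under 2-fold with a higher floor for Nrp1 (-0.97 with the floor 2 times as high), Il2ra (-0.97 at 2 times the array median) and Ebi3 (-0.75 at 4 times), but not for Tnfrsf4. The anti-inflammatory cytokine Il10 went the other way, with signals of 5.45 and 19.3, 3.54-fold higher, as did Ikzf2, the transcription factor Helios (2.45-fold). The 3 probe sets of Ikzf2 gave log2 differences between 0.05 and 1.29. Foxp3, the regulatory T cell transcription factor, chosen after its values were seen, was near the array median on both arrays, at 1.10 and 0.69.

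Inhibitory receptors and exhaustion genes were split, with a median of -0.11 over 15 members (percentile 8.64), 4 higher, 3 lower and 8 between. Lag3, an inhibitory receptor that binds MHC class II, had signals of 6.62 and 19.6 and was 2.96-fold higher, and Cd200 was 2.39-fold higher, along with Cd244 and Tox. Btla (4.03-fold) and Pdcd1, which encodes PD-1 (3.74-fold), were lower, with Nrp1, although Pdcd1 was at -0.57 with the floor at 4 times the array median. T cell receptor and proximal signalling genes had a median of 0.11 over 24 members (percentile 83.3), with 2 higher, 2 lower and 20 between. Cd28 had signals of 59.6 and 2.35, and its 3 probe sets gave log2 differences between -4.70 and -4.38. Cd2, an adhesion and costimulatory molecule, was 6.78-fold lower (62.3 and 9.18). Cd7 was 4.55-fold higher (67.5 and 307) and Cd3e 2.01-fold higher (0.98 on the log2 scale with the raw signals). Gut homing and tissue residency genes had a median of 0.10 over 15 members (percentile 68.8), with 0 higher, 3 lower and 12 between. The chemokine receptor Cxcr6 was 3.71-fold lower (169 and 45.5), Gpr15, a homing receptor of the large intestine, 2.60-fold (-0.30 on the log2 scale with the floor at 2 times the array median) and Ahr, the aryl hydrocarbon receptor, 2.12-fold lower.

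**Figure D2:**
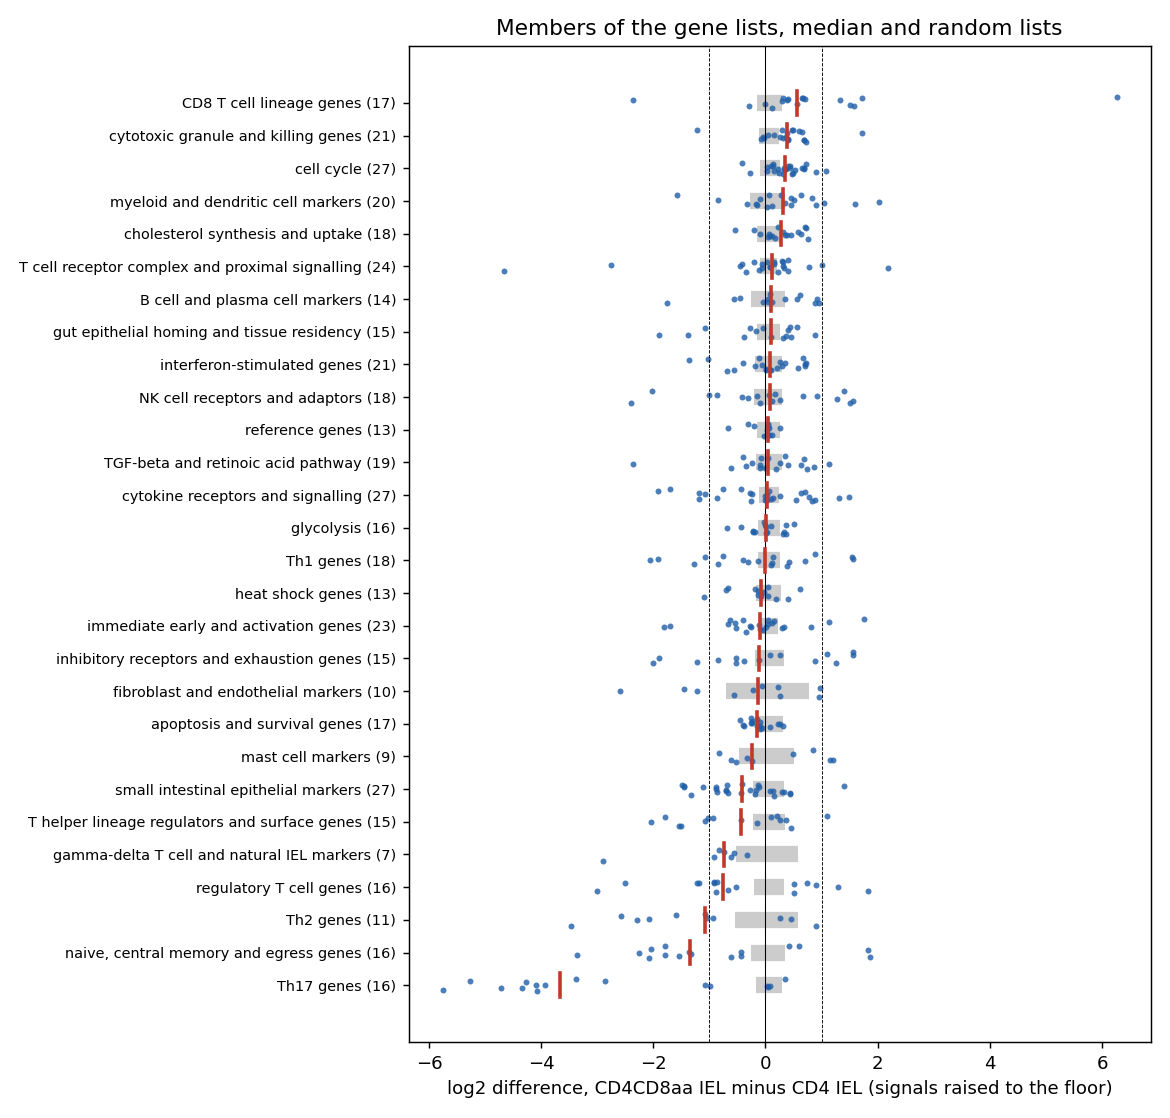
Log2 differences (CD4CD8aa IEL minus CD4 IEL, signals raised to the floor) of the detected members of the 28 gene lists, with the number of members in brackets. Blue points are genes, red bars the medians, gray bands the central 95% of the medians of 10000 random lists matched on signal, and dashed lines 2-fold differences. The Th17 list has the lowest median (-3.66) and the CD8 lineage list, which includes Cd8a, the highest (0.56).

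Cell cycle genes were slightly higher as a group, with a median of 0.35 over 27 members (percentile 99.8), 25 of them above 0. Only Bub1b, a mitotic checkpoint kinase, reached 2-fold (2.10-fold), none was 2-fold lower, 26 lay between, and another probe set of Bub1b gave -1.26. Cholesterol synthesis genes had a median of 0.27 over 18 members (percentile 97.0, and above the central 95% of the random lists under 3 of 11 alternatives) and no member at 2-fold. Cytokine receptors and signalling genes had a median of 0.03 over 27 members (percentile 34.2), with 2 higher, 5 lower and 20 between, among them Il18r1 and Il6st, the shared receptor chain gp130 (1.49, or 0.21 as the median over its probe sets). TGF-beta and retinoic acid pathway genes had a median of 0.04 over 19 members (percentile 40.9), with Tgfbr3 2.19-fold higher, Dhrs3, a retinaldehyde reductase, 5.15-fold lower (-0.39 on the log2 scale with the floor at 4 times the array median) and 17 between. The difference of Tgfbr3 was 0.71 on the log2 scale as the median over its probe sets. Immediate early and activation genes had a median of -0.10 over 23 members (percentile 3.66), with 2 higher (led by Nr4a2, 3.40-fold), 2 lower (led by Dusp2, 3.51-fold) and 19 between. The 6 probe sets of Nr4a2 gave log2 differences between -0.49 and 2.24. Interferon-stimulated genes had a median of 0.09 over 21 members (percentile 62.3), with 0 higher, 2 lower (led by Ifit3, 2.58-fold, or -0.18 on the log2 scale with the floor at 2 times the array median) and 19 between. Heat shock genes had a median of -0.09 over 13 members (percentile 9.46), of which Hspa1a was 2.13-fold lower and 12 lay between. No member of the apoptosis and survival list (17 genes, median -0.15, percentile 2.70), the glycolysis list (16 genes, 0.01, percentile 29.9) or the reference gene list (13 genes, 0.04, percentile 50.8) reached 2-fold.

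Markers of other cell types were measured as a check on the purity of the sorts. Small intestinal epithelial markers had a median log2 difference of -0.42 over 27 members (percentile 0.12), with 1 higher, 5 lower and 21 between. Of those with the highest signals, Reg3b, an antimicrobial lectin, had 60.8 and 22.3 (-1.45), Krt18, a keratin, 13.3 and 4.74 (-1.49) and Lyz1, a lysozyme of Paneth cells, 15.1 and 11.3 (-0.42), though Lyz1 gave 1.13 when probe sets prone to cross-hybridisation were left out. Vil1 was higher (1.40) from a signal of 0.43, and by 0.49 with the floor 2 times as high. Gamma-delta T cell and natural IEL markers had a median of -0.74 over 7 members (percentile 0.21), all below 0, with 1 at least 2-fold lower (Cd163l1, -2.89, or -0.27 with the floor at 4 times the array median) and 6 between. Only these 7 of the 13 genes of the list matched a probe set. Tcrg-V4, a gamma chain segment, was bright in both (159 and 126, -0.33), and Kit had 18.5 and 10.5 (-0.82). Tcrg-V1, a gamma chain segment outside the list that was chosen after its values were seen, was higher (77.5 and 198, 1.35). B cell markers had a median of 0.10 over 14 members (percentile 61.0), with 0 higher, 1 lower (Cd79b, -1.76, or -0.83 with the floor 2 times as high) and 13 between, and the highest signals were those of the MHC class II genes H2-Aa (26.0 and 27.0), Cd74 (12.3 and 18.9) and H2-Eb1 (11.9 and 17.6). The RAG-knockout recipients make no T or B cells of their own. Signals of the gamma-delta and B cell lists therefore do not show that such cells were present. Myeloid and dendritic cell markers had a median of 0.31 over 20 members (percentile 96.0), with 3 higher (led by C1qc, at least 4.07-fold, or 1.02 on the log2 scale with the floor 2 times as high), 1 lower (Cd14, -1.57) and 16 between, with the highest signals at Cst3 (39.3 and 34.8), Csf1r (9.79 and 10.2) and C1qb (6.41 and 3.56). Mast cell markers had a median of -0.24 over 9 members (percentile 16.2), with 2 higher (led by Mcpt4, at least 2.32-fold, or 0.21 on the log2 scale with the floor 2 times as high) and 7 between, and besides Kit, which also stands in the gamma-delta list, none reached 2 times the array median. Tpsb2 had 0.88 and 1.24. Fibroblast and endothelial markers had a median of -0.14 over 10 members (percentile 30.7), with 0 higher, 3 lower and 7 between, all under 4 times the array median on both arrays. Pecam1 was at least 6.03-fold and Pdgfra at least 2.75-fold lower, but Pecam1 by -0.27 with the floor at 2 times the array median and Pdgfra by -0.46 with the floor 2 times as high, and Acta2 had 2.41 and 2.88. Of all 28 lists, 3 lay above and 7 below the central 95% of their random lists. The 1.4 that would lie outside by chance assumes members that vary independently. Several lists share members, and the CD8 lineage list holds the marker of the sort, so the count is a description and no test.

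The 10 largest differences towards lower signal in CD4CD8aa IEL included Ctla2a, a cysteine protease inhibitor of T cells (42.0 and 0.52, 81.5-fold), Il17a, S100a4, a calcium-binding protein of motile cells (57.5 and 1.203, 47.8-fold), and Kbtbd11 (122 and 3.12, 38.9-fold). For Kbtbd11, 1 of its 4 detected probe sets gave 0.59 and the median over them was -1.32. The others were Il17re, the neutrophil chemokine Cxcl3 (at least 30.9-fold), the hypoxia-inducible factor Epas1 (at least 28.2-fold), Ltb4r1, Cd28 and the chemokine receptor Ccr1 (at least 21.1-fold, with -0.75 at its other probe set). The order depends on the floor: with the floor 2 times as high Ctla2a was at -5.71, behind Il17a at -5.76, and at 2 times the array median Ctla2a was at -4.39, S100a4 at -4.85, Cxcl3 at -2.63, Epas1 at -2.50 and Ccr1 at -2.08. In the other direction Cd8a was followed mostly by genes that were dim on the CD4 array, among them Wdtc1 (8.998-fold), 2410002I01Rik (7.28-fold), Igsf3 (6.27-fold), Hcn3 (at least 6.18-fold), C76614 (at least 6.06-fold), C130023C23Rik (at least 5.84-fold) and Slco2b1 (5.62-fold, with -0.27 at its other probe set). For Igsf3 the median over its 3 detected probe sets was 1.06 on the log2 scale. The uncharacterised transcript 2900001G08Rik was bright on both arrays (8.84 and 50.04, 5.66-fold). With the floor at 2 times the array median most of the others were under 2-fold, with Wdtc1 at 0.90, 2410002I01Rik at 0.67, Hcn3 at 0.31, C76614 at 0.28, C130023C23Rik at 0.22 and Slco2b1 at 0.97, while Igsf3 was at 1.61, or 0.61 at 4 times the median. At the floor of 2 times the median, the 10 largest differences towards higher signal included Cd8a, 2900001G08Rik, Cd7 and Plcg2, the last chosen after its values were seen.

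These differences rest on 1 array per population, so differences between populations and between RNA preparations cannot be told apart. The 3′ to 5′ signal ratio, which grows as RNA degrades or labelling shortens, was 1.501 in CD4 IEL and 2.03 in CD4CD8aa IEL for beta-actin, and 3.39 and 4.78 for Gapdh.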

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

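Both tests of an explanation in this part were chosen after the results were seen. The arrays carry probe sets for bacterial transcripts that belong to no mouse gene and enter no comparison of the report. Those for the Bacillus subtilis transcripts dap, lys, phe and thr, which can be added to a sample's RNA before labelling, were bright in CD4 IEL and had a median log2 difference of -3.08 in CD4CD8aa IEL (8.48-fold lower, between 2.39-fold and 16.8-fold over 24 probe sets). A difference in hybridisation or scanning is argued against by the controls that are added at that step (bioB, bioC, bioD and cre), whose 18 probe sets had a median of 0.28 with an SD of 0.134. A smaller amount of these transcripts relative to the sample's own RNA stays open as a candidate explanation: 100% of the 24 probe sets were lower, but that restates what was seen and decides nothing. The median was -2.61 for probe sets at the 3′ end, -3.33 in the middle and -3.50 at the 5′ end, but this order did not hold for every transcript: 1 series of probe sets for lys gave -2.53 at the 3′ end and -2.33 at the 5′ end, and 1 for thr -3.04 and -2.99. Whether more sample RNA or less control RNA went into the CD4CD8aa labelling was not tested, and no biological explanation was tested.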

How the results depend on the processing

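The floors at 2 and at 4 times the array median and the CD8 lineage list without its sort marker were chosen after the results were seen. All 28 list medians and both counts moved little (counts by under 1.5 times) under median centring, quantile normalization, the raw signals, no detection filter and without _x_at probe sets, and matching random lists on the brighter array left every list on its side of the central 95%. Median differences of all genes shifted by under 0.1 under each scaling. The CD8 lineage, cytotoxic and cell cycle lists stayed above, and the Th17, naive, helper lineage, regulatory, epithelial and gamma-delta lists below, the central 95% of their random lists under all 11 alternatives to the list values, and Th2 under 10. Of lists inside it, cholesterol synthesis lay above it under 3 alternatives (percentile 97.9 with quantile normalization, 98.6 and 98.4 with the floors at 2 and 4 times the median), myeloid markers above it under 2 (98.0 without a floor, 97.7 with the median over probe sets), and apoptosis genes below it under 1 (1.75 with quantile normalization). Counts of genes higher and lower were 2995 and 2505 at 1.5-fold and 243 and 326 at 3-fold, by construction. Without a floor they were 1998 and 1960, and medians were -0.93 for the helper list, -1.67 for naive, -2.07 for Th2, 0.45 for B cells and -0.50 for mast cells. With the floor 2 times as high the counts were 446 and 483, all among the main ones, and medians -0.93 (helper), -0.85 (naive), -3.02 (Th17), -0.76 (Th2), 0.19 (TGF-beta) and 0.18 (mast cells). Detection on both arrays gave 586 and 589, and -3.13 (Th17), -0.23 (epithelial) and 0.12 (myeloid). The median over probe sets gave -1.16 (naive), -0.21 (Th1, percentile 0.75), -0.60 (regulatory), -0.079 (TGF-beta), -0.17 (cytokine receptors, percentile 2.01) and -0.21 (heat shock), where the cause was not tested. The floor at 2 times the median gave 204 and 219, and -0.75 (naive), -2.45 (Th17), 0.086 (inhibitory receptors) and -0.82 (mast cells, 1 member). The floor at 4 times gave 141 and 140, and -0.28 (helper), 0.27 (NK receptors), 0.21 (homing), -0.36 (naive), 0.095 (Th1), -1.45 (Th17), -0.15 (Th2), -0.48 (regulatory), 0.18 (inhibitory receptors), 0.32 (B cells), 0.060 (myeloid), -0.82 (mast cells) and -0.33 (gamma-delta). The fibroblast list had no member left there. The CD8 lineage list had a median of 0.48 without Cd8a and of 0.40 without Cd8a and Cd8b1, above the central 95% in both. Higher floors shrink differences and drop dim genes by construction. No named gene that was at least 2-fold apart changed direction under any alternative. Of the 69 such genes still detected with the floor at 2 times the median, 15 were under 2-fold. Floors and detection filters cannot reverse a direction, and the scalings shifted values little. Only the choices of probe set could therefore have reversed a 2-fold difference. Lyz1, under 2-fold in the main values, did change direction without _x_at probe sets, from -0.42 to 1.13. Low signal limits the dim genes, for which the floor sets the fold. No paired analysis was possible because each group has 1 array.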

Other observations

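The genes of this paragraph and the next, and all 3 tests of an explanation further on, were chosen after the values were seen. Further genes had large differences, and since they were picked for their values they stand for no gene group. S100a6, a calcium-binding relative of S100a4, had 49.2 in CD4 IEL and 2.84 in CD4CD8aa IEL (17.3-fold lower), the annexin Anxa1 8.86 and 0.60 (14.7-fold), and the chemokine receptor Ccr2 21.4 and 1.14 (18.7-fold, with -1.21 on the log2 scale at the least different of its 4 probe sets). Gpr183, the oxysterol receptor that guides lymphocytes, had 38.7 and 4.66 (8.30-fold lower), and the adhesion molecules Cd44 and Itgal were 2.13-fold and 2.07-fold lower from high signals. The interferon-induced membrane proteins Ifitm1, Ifitm2 and Ifitm3 were 4.05-fold, 3.74-fold and 9.58-fold lower, although the interferon-stimulated gene list had a median of 0.09. Il2, the T cell growth factor, had 7.97 and 0.68 (11.7-fold lower). Tnfrsf25, which encodes DR3, was 14.3-fold and Tnfsf8, which encodes CD30 ligand, 4.18-fold lower.

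Genes that were bright in CD4CD8aa IEL and higher there included Plcg2, a phospholipase C best known from B and NK cells (23.9 and 107, 4.47-fold), Scin, an actin-severing protein (40.8 and 142, 3.49-fold), Ncf1, a subunit of the phagocyte NADPH oxidase (25.7 and 76.1, 2.96-fold, and 0.62 on the log2 scale at the least different of its 3 probe sets), and Litaf (79.5 and 220, 2.77-fold, with 0.07 at 1 of its 3 probe sets). The NF-kappa-B cofactor Bcl3 was 2.42-fold higher. Pmepa1, a target of TGF-beta signalling, was 2.19-fold higher and its 3 probe sets gave between 0.89 and 1.19, while the TGF-beta and retinoic acid list had a median of 0.04. A probe set for the gamma chain segment Tcrg-V1 had 77.5 and 198 (2.56-fold higher), and that for Tcrg-V4 was 1.26-fold lower.

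Noise of single probe sets is argued against as the source of the low Th17 signals in CD4CD8aa IEL, for the genes that have other probe sets. The 10 further detected probe sets of 5 of the 11 lower Th17 genes had a median log2 difference of -2.83, and all 10 were at least 2-fold lower, where same-gene probe sets had an SD of 0.615. A candidate source other than the T cells themselves is CD4-expressing innate lymphoid cells, which share Ccr6 and Il17a with Th17 cells and may pass a sort on CD4, since they survive in RAG-knockout mice and the gates of the sort are not given. Of 6 markers of these cells, 4 also stand in other lists used here and only 2 reached 2 times the array median, with a median of -1.49: Kit had 18.5 and 10.5 and Tnfsf11 17.7 and 3.94. The other detected probe set of Kit gave -0.38 and that of Tnfsf11 -0.82, so the median depends on the probe sets used. With so few bright markers the explanation stays open, as does a true difference between the T cell populations, which is untested with 1 array each.

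The small intestinal epithelial markers were lower in CD4CD8aa IEL as a group, with a median of -0.42 also over the 15 that reached 2 times the array median. Less epithelial RNA in that sort may be the reason, although both populations were sorted after a Percoll gradient, which should leave few epithelial cells, and how many remained is not known. It would lower all markers alike, and the SD of their differences, 0.627, was 1.27 times the 0.494 of same-gene probe sets at their signal, with Reg3b and Krt18 lower (-1.45 and -1.49) and Fabp1, the fatty acid binding protein of enterocytes, at 0.43. This is too close to the technical spread to decide, and a change in the epithelium next to the cells stays open as well. None of the 29 markers stands in another list.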
